A study of Folsomia candida with 10 samples.

How the data were processed

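The data were 10 two-channel Agilent arrays, scanned and quantified by the authors with Feature Extraction 9.5.1.1 per the file headers. The signal and background columns of each array were intensity, the mean brightness of a spot and its median local background on a linear scale with no normalization by the authors. The scanner's LogRatio column was log10 of the Cy5 over Cy3 ratio after the authors' background subtraction and dye normalization, per the file headers. The deposited value table was log2 Cy5 over Cy3, for which the authors' processing notes name limma 2.9.2 and state no method. It held 15742 values per array, with 0 columns that could not be mapped to an array and medians of 0.004 to 0.015. Its values correlated with the scanner's log ratios at 0.893 to 0.948 and with the log ratios computed here at 0.991 to 0.997. Both were taken across the tested genes of each array and bore out its direction. The slope of the log ratios computed here on its values was 0.9 to 0.939, which bore out its log2 scale.

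The analysis started from the intensities, in R 4.3.3 with limma 3.58.1. Of 15743 spots, 15207 were gene spots and 536 controls. Background was corrected with normexp and an offset of 50, spots marked by the scanner software as non-uniform or as outliers (514 to 587 per array) were left out, and ratios were normalised by loess within each array. The 3 spots of a probe were averaged. A probe was tested if at least 2 of its 3 spots stood well above background in at least 4 of the 20 channels. Replicate spots correlated at 0.843 to 0.984 over probes, and at most 1 spot per array was saturated.

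Each log2 ratio was modelled as the difference of its Cy5 and Cy3 diets, with 4 diet coefficients against the Cladosporium diet and 1 dye intercept, which left 5 residual degrees of freedom. The moderated test of limma was two-sided and used Benjamini-Hochberg adjustment at 0.05 within each comparison. The comparisons, the gene groups, the rule for naming genes and most alternative settings were fixed before the data were examined, and the other settings were added after. The median residual SD was 0.374 log2, and the median SE of a difference between 2 diets was 0.228. The normalised signals per channel, used for levels and for the separate-channel fit of limma, were quantile-normalised on average intensity (Aquantile), and the correlation of the channels within a spot was -0.0089.

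By the naming rule, a comparison names up to 10 called genes with the largest rise and 10 with the largest fall, with up to 4 called members of each gene group. Where fewer than 5 named genes are called, the 5 described genes with the smallest unadjusted p are named as values not passing the test. Probes without a database hit were not eligible, and some of them had a smaller p. Names are the descriptions of old database hits in other organisms, some of them truncated, and not F. candida gene symbols. 0 probes matched the reference table of 27231 genes, so genome positions were not analysed.

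The 24 gene groups were matched to the descriptions by fixed expressions, with hyphens removed from both since the files print none: cytochrome P450, esterases and other phase I enzymes, glutathione S-transferases, UDP-glycosyltransferases and sulfotransferases, ABC transporters, antioxidant defence, heat shock proteins, metal binding, β-lactam biosynthesis, proteases, carbohydrate hydrolases, chitin and cuticle, egg proteins, hormone and moulting signalling, lipid metabolism, innate immunity, ribosomal proteins, translation factors, oxidative phosphorylation, proteasome and ubiquitin, cell cycle, muscle, nervous system, and fungal or bacterial transcripts. The fungal or bacterial group held descriptions that name Aspergillus, Emericella, Cladosporium, Wolbachia or Rickettsia, or hold the words fungal or bacterial. Probes with hits in other fungi or bacteria, such as Penicillium or Bacillus, were outside it. Groups with at least 5 tested genes (19 of 24) were tested with camera at a preset correlation of 0.01, with camera at a correlation estimated per group, and with fry, each adjusted over the groups of a comparison. Of the 24 calls by camera over the 11 comparisons, 0 held with the estimated correlation or with fry.

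In a self-test with simulated independent errors of the measured size, 200 of 4174 genes were changed between the wild-type and Cladosporium diets. The fit recovered 43% of them at 2-fold, 82% at 4-fold and 95.5% at 8-fold. Of the unchanged simulated genes, 4.86% to 5.33% had an unadjusted p under 0.05, against 0.5% to 1.44% of genes in the real comparisons. The errors of the real data thus differ from the simulated ones, and these shares are not the sensitivity of the study.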

Results

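Transcript levels were measured in whole springtails (Folsomia candida, Berlin strain) that had fed on 5 fungal diets. Each sample was the RNA of a pool of about 30 animals, 23 days old when feeding began and 28 days old after 5 days of feeding. The diets were the mould Cladosporium cladosporoides, which the authors name as the reference (the Cladosporium diet), wild-type Aspergillus nidulans (the wild-type diet), an A. nidulans strain without LaeA (the deletion diet), and C. cladosporoides mixed with either Aspergillus strain (the wild-type mixture and the deletion mixture). LaeA is a global regulator of fungal secondary metabolism, so the pair of Aspergillus strains may differ in the metabolites it makes, which were not measured here. Each diet had 4 pools, 2 labelled with Cy3 and 2 with Cy5, and every pair of diets met on 1 of 10 two-channel arrays. Arrays 4 and 10 lay on 1 slide and the other 8 on another.

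Each array held 5069 gene probes, each printed as 3 spots. Of these, 2321 carried the description of a database hit from another organism and 2748 had no hit. The median signal per array was 110 to 311.5 in the Cy3 channel and 320.5 to 727 in the Cy5 channel, and 68.0% to 82.9% of gene spots stood well above background. The test covered 4174 probes (82.3%), of which 1991 had a description, while 693 probes were above background in no channel. The median 95% half-width of a fold change between 2 diets was 0.53 log2 (1.45-fold), which the number of arrays limits.

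Across all 11 comparisons limma called 0 of 4174 genes at an adjusted p under 0.05, and the test for any difference between diets called 0 too. The genes at an unadjusted p under 0.05 numbered 21 to 60 per comparison, fewer than the 208.7 that 5% of the genes would give. A separate-channel fit also called 0 in every comparison. Counting the 3 spots of a probe as separate observations, which treats copies of a spot as replicates, called 100 to 718, and 0 to 49 with the correlation of the copies modelled. Array weights called 0, but raised the unadjusted count above 208.7 in 4 comparisons: to 469 (deletion against Cladosporium), 352 (deletion against wild type), 254 (wild-type mixture against wild type) and 277 (wild-type mixture against its midpoint). Weights whose estimation did not converge called 42 for the deletion against the Cladosporium diet. A dye term for each slide called 0, and the 8 arrays of slide 1 alone called 0 except for 1 gene, Fcc05893, a probe without a hit (deletion against Cladosporium diet, log2 3.04, adjusted p = 0.0373, against 2.27 and adjusted p = 1 on all arrays). Slide 2 held too few arrays for a fit. With each array left out in turn limma still called 0, but the unadjusted count reached 633 (deletion mixture against Cladosporium), 572 (deletion mixture against its midpoint) and 507 (between the mixtures) without array 10, and 311 (deletion mixture against Cladosporium) and 214 (the difference of the LaeA effects) without array 4. Over all comparisons and left-out arrays the unadjusted counts ran from 2 to 633. The SD of log2 ratios over genes was 0.846 on array 4 and 0.732 on array 10, against 0.366 to 0.586 on the others. Named genes below, chosen among probes with a description, are therefore given as values not passing the test, and no probe could be placed on a genome.

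**Figure D1:**
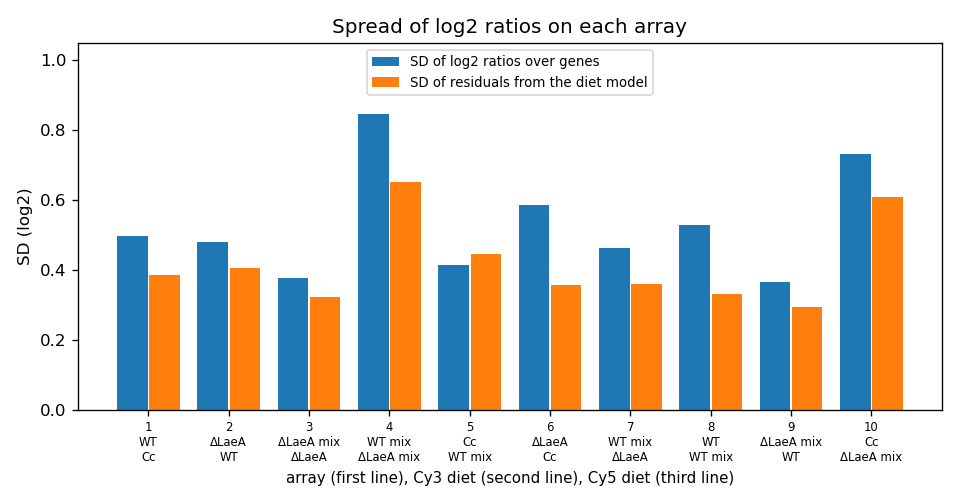
Bars give, for each of the 10 arrays with its Cy3 and Cy5 diets, the SD over tested genes of the log2 ratio and of the residual from the diet model, both in log2 units. Arrays 4 and 10 stand at 0.846 and 0.732, and the residual SD at 0.652 and 0.609, against 0.295 to 0.445 for the other residuals.

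The comparison of the wild-type diet with the Cladosporium diet addressed what an Aspergillus with LaeA does to the animals. Of 3 probes similar to isopenicillin N synthase, the enzyme that closes the β-lactam ring in penicillin synthesis, 2 were higher on the wild-type diet, and the other, Fcc05602, stood at log2 -0.02 (SE 0.21). Fcc00057 differed by log2 1.53 (SE 0.45, 95% CI 0.48 to 2.58) and Fcc01821 by 1.33 (SE 0.40, 95% CI 0.39 to 2.27). The signal of Fcc00057 was 11.87 ± 1.55 log2 (SD, n = 4) on the wild-type diet and 11.10 ± 0.97 on Cladosporium, and a single wild-type pool, on array 1, stood at 14.18 against 10.91 to 11.28 for the others. Without array 1 the differences were 0.98 and 0.69, and the separate-channel fit gave 0.76 and 0.58. Lower on the wild-type diet were Fcc06270, similar to an uncharacterised fly protein (GA17413), at log2 -0.89 (SE 0.19, 95% CI -1.33 to -0.44), and uncharacterised mosquito-like Fcc01333 (-1.12, SE 0.33) and Fcc06011 (-0.89, SE 0.28). On the 4 arrays carrying the Cladosporium diet, these 3 probes were lower on the other diet in 4 of 4. They were named by their p in a fit that held these arrays, so the shared direction is no separate support. In the separate-channel fit Fcc06270 stood at -0.63 and Fcc01333 at -0.70.

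Among the gene groups fixed before the data were examined, 5 of 7 probes of the β-lactam biosynthesis group were higher on the wild-type diet (median log2 0.43). They included Fcc00170, similar to the synthetase that builds the penicillin tripeptide, at 1.27 (SE 0.68). By its matched words the group also held Fcc01834, similar to a bacterial β-lactamase, which is not a biosynthesis enzyme. The set test camera called this group (adjusted p = 0.0131), with adjusted p = 0.505 with an estimated correlation. Adjusted over the list alone, 2 of the 7 probes passed, the isopenicillin N synthase probes Fcc00057 and Fcc01821 (smallest adjusted p = 0.0417), against 0 over all genes. These 2 probes share a description and their ratios correlated at 0.97 over arrays. They may report 1 transcript, while the adjustment counted them as separate tests. Ribosomal proteins were higher in 32 of 36 genes, by a median of 0.15 (camera adjusted p = 0.000326, adjusted p = 0.505 with an estimated correlation), with S12 (Fcc02740) at 0.30 (SE 0.17). Cytochrome P450 genes, which oxidise foreign compounds, were lower in 10 of 11 by a median of -0.18 (camera adjusted p = 0.0395, adjusted p = 0.505 with an estimated correlation), with a 4C1-like gene (Fcc01417) at -0.52 (SE 0.25). Carbohydrate hydrolases were lower in 8 of 11 (median -0.31, camera adjusted p = 0.0598), among them the cellulase-like Fcc05266 at -2.09 (SE 1.17). Muscle genes were lower in 7 of 7 (median -0.38, adjusted p = 0.0598), while nervous system genes were split 3 to 5 (median -0.05, mean 0.01, adjusted p = 0.959). Probes of the fungal or bacterial group, most of them with an Aspergillus hit, were higher in 11 of 13 (median 0.11, adjusted p = 0.149). Of 3 egg protein probes 1 was higher and 2 were lower (median -0.21). The β-lactam call was lost without array 1, 5, 9 or 10 (adjusted p 0.0632 to 0.384), the ribosomal call without array 1 or 5 (0.336 to 0.643), and the P450 call without array 2, 5, 6, 8, 9 or 10 (0.0632 to 0.454). With a dye term for each slide the β-lactam and P450 groups both had adjusted p = 0.0552 and ribosomal proteins 6.68e-06, and on slide 1 alone 0.235, 0.235 and 3.09e-12. These values, here and in the comparisons below, are from camera at the preset correlation of 0.01. The estimated correlation of ribosomal proteins was 0.47 on all arrays and was not used in these settings, so their small values do not show a shift.

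Between these diets limma called 0 genes (smallest adjusted p = 0.987), 60 genes had an unadjusted p under 0.05, 17 higher and 43 lower, and the separate-channel fit called 0. The count of 60 ran from 21 to 155 with each array left out and was 188 in the separate-channel fit.

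**Figure D2:**
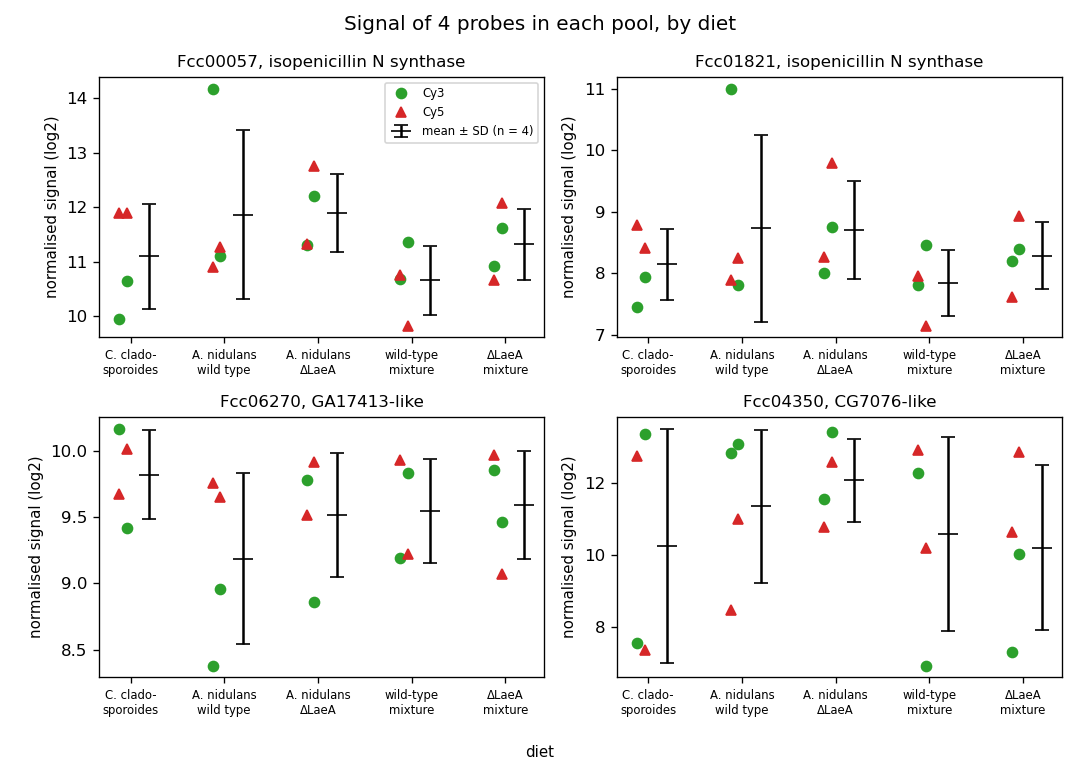
Points are the normalised log2 signal of each of the 4 pools per diet for Fcc00057, Fcc01821, Fcc06270 and Fcc04350, circles Cy3 and triangles Cy5, with bars for mean ± SD (n = 4). The wild-type pool on array 1 stands at 14.18 for Fcc00057, and the Cladosporium pools of Fcc04350 range from 7.35 to 13.37.

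The deletion diet against the Cladosporium diet asked the same of an Aspergillus without LaeA. The widest difference among named genes was Fcc04350, similar to the fly gene CG7076, higher by log2 5.88 on the deletion diet (SE 1.31, 95% CI 2.79 to 8.96). Its level was 12.09 ± 1.16 log2 (SD, n = 4) on the deletion diet and 10.26 ± 3.26 on Cladosporium, where the pools lay at 12.77, 7.54, 7.35 and 13.37, and the separate-channel fit gave 1.79. Fcc06270 was lower, at log2 -0.89 (SE 0.19), and -0.30 in the separate-channel fit. Fcc00137, similar to bacterial cyclopropane fatty acyl phospholipid synthase, which modifies membrane lipids, was higher by 0.75 (SE 0.20), but by 0.06 in the separate-channel fit. Isopenicillin N synthase Fcc00057 was higher by 1.46 (SE 0.45), 1.19 without array 1 and 2.43 without array 6, 0.79 in the separate-channel fit and 0.31 on the array that carried both diets.

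Muscle genes were lower on the deletion diet in 6 of 7, by a median of -0.54 (camera adjusted p = 0.00434, adjusted p = 0.775 with an estimated correlation). Myosin 3 light chain (Fcc00218) stood at -0.54 (SE 0.21), titin (Fcc05061) at -0.78 (SE 0.53) and tropomyosin (Fcc01221) at -0.26 (SE 0.20). Nervous system genes were higher in 6 of 8 (median 0.08, adjusted p = 0.526), egg proteins in 1 of 3 and probes of the fungal or bacterial group in 6 of 13 (median -0.05, mean 0.05, adjusted p = 0.772). The muscle call was lost without array 10 (adjusted p = 0.59) and on slide 1 alone (0.149), and was 0.0163 with a dye term for each slide. Limma called 0 genes (smallest adjusted p = 1), 45 had an unadjusted p under 0.05, 33 higher and 12 lower, and the separate-channel fit called 0. The count of 45 ran from 19 to 205 with each array left out.

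The wild-type mixture against the Cladosporium diet asked what adding wild-type Aspergillus to the reference food does. All 5 named genes with the smallest p were lower on the mixture. Fcc06270 stood at log2 -0.77 (SE 0.19). Laminarinase-like Fcc00670, an enzyme type that splits β-glucans of fungal walls, stood at -1.11 (SE 0.41, 95% CI -2.07 to -0.15). The peptidases were ADAM33-like Fcc00971 at -0.93 (SE 0.33) and angiotensin converting enzyme Fcc05882 at -0.73 (SE 0.27). Isopenicillin N synthase Fcc00057, chosen after its values were seen, was at 10.66 ± 0.63 log2 (SD, n = 4) on this mixture, below its 11.10 ± 0.97 on Cladosporium, whereas the model of ratios within arrays put it 0.60 higher (SE 0.45, 95% CI -0.45 to 1.65) and the array carrying both diets 0.81 higher. The separate-channel fit gave values nearer 0 for the named genes: -0.27 for Fcc06270, -0.38 for Fcc00670, -0.27 for Fcc00971 and -0.21 for Fcc05882.

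Muscle genes were lower in 6 of 7 (median -0.54, camera adjusted p = 0.00512, adjusted p = 0.731 with an estimated correlation), with myosin 3 light chain (Fcc00218) at -0.40 (SE 0.21). Glutathione S-transferases, which conjugate foreign compounds, were lower in 11 of 15 (median -0.25, camera adjusted p = 0.03, adjusted p = 0.731 with an estimated correlation). Esterases and other phase I enzymes were lower in 9 of 11 (median -0.33, camera adjusted p = 0.03, adjusted p = 0.731 with an estimated correlation), with aldehyde oxidase (Fcc02034) at -0.67 (SE 0.41) and acetylcholinesterase (Fcc02050) at -0.79 (SE 0.51). Carbohydrate hydrolases were lower in 7 of 11 (median -0.36). Nervous system genes were split 4 to 4 (median -0.01, mean 0.02, adjusted p = 0.81) and probes of the fungal or bacterial group 7 to 6 (median 0.01, mean -0.04, adjusted p = 0.81), and 2 of 3 egg protein probes were higher. The muscle call was lost without array 4 or 10 (adjusted p 0.518 to 0.538), and the glutathione S-transferase and esterase calls without array 4, 6, 7 or 10 (0.0513 to 0.637 and 0.0609 to 0.628). Given a dye term for each slide the muscle group had adjusted p = 0.00541 and the others 0.0341, and on slide 1 alone 0.722 and 0.977. The limma fit called 0 genes (smallest adjusted p = 0.994), 30 had an unadjusted p under 0.05, 13 higher and 17 lower, and the separate-channel fit called 0.

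The deletion mixture against the Cladosporium diet asked the same with the LaeA-deficient strain added. The mitochondrial NADH dehydrogenase subunit 4 (Fcc04995) was lower, at log2 -0.50 (SE 0.17). Peroxisomal enoyl-CoA hydratase 1 (Fcc01668), an enzyme of fatty acid breakdown, was higher by 0.43 (SE 0.15), as was a DC2-like protein (Fcc04101, 0.43, SE 0.15). In the separate-channel fit these 3 stood at -0.23 (Fcc04995), 0.45 (Fcc01668) and 0.30 (Fcc04101). Over all settings they ran from -0.81 to -0.23 (Fcc04995), 0.15 to 0.51 (Fcc01668) and 0.30 to 0.53 (Fcc04101). The antifungal peptide spodomicin (Fcc04856) was lower, but was above background in 5 of the 20 channels and in 0 of the 4 deletion mixture pools, and its value moved from -2.29 to -0.25 with the processing. Isopenicillin N synthase Fcc00057 was higher by 1.24 (SE 0.45), 0.96 to 1.72 with each array left out, and by 0.21 in the separate-channel fit. On the 4 arrays carrying the Cladosporium diet it was 2.27, 0.81, 0.31 and 1.44 higher on the other diet. Of 4166 genes, 9.7% lay on 1 side on all 4 arrays, where even and independent signs give 12.5%. Cladosporium was in Cy5 on 2 of these arrays and in Cy3 on 2, so dye effects of a probe lower the share that chance gives.

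Ribosomal proteins were higher on the deletion mixture in 33 of 36 genes, by a median of 0.17 (camera adjusted p = 3.36e-05, adjusted p = 0.748 with an estimated correlation), with S9 (Fcc06150) at 0.54 (SE 0.25). Innate immunity genes were lower in 4 of 5 (median -0.28, camera adjusted p = 0.0451, adjusted p = 0.656 with an estimated correlation). They included the antimicrobial peptide Alo2 (Fcc05968) at -0.80 (SE 0.29) and prophenoloxidase (Fcc01326), the precursor of the melanising enzyme, at -0.28 (SE 0.18). Muscle genes were lower in 6 of 7 (median -0.22, adjusted p = 0.105), nervous system genes higher in 7 of 8 (median 0.07, adjusted p = 0.254), egg proteins higher in 3 of 3 (median 0.06) and probes of the fungal or bacterial group higher in 9 of 13 (median 0.05, adjusted p = 0.407). The ribosomal call was lost without array 4 or 5 (adjusted p 0.179 to 0.559) and the immunity call without array 3, 4, 5, 6 or 10 (0.0667 to 0.807). Under a dye term for each slide ribosomal proteins had adjusted p = 3.64e-07 and immunity genes 0.781, and on slide 1 alone 1.23e-09 and 0.999. In this comparison limma called 0 genes (smallest adjusted p = 0.999), 40 had an unadjusted p under 0.05, 16 higher and 24 lower, and the separate-channel fit called 0.

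These 4 comparisons share the Cladosporium pools, and 0 genes were called in more than 1 of them. The correlation of their fold changes across 4150 genes, which are not independent replicates, was 0.46 to 0.75, and simulated data without diet differences gave 0.50 to 0.51. The highest, 0.75, joined the deletion diet and the wild-type mixture, and ran from 0.50 without array 4 to 0.82 without array 1. That of the wild-type and deletion diets, 0.58, ran from 0.19 without array 2 to 0.76 without array 6. Those of the mixtures (0.54), of the wild-type diet with the wild-type mixture (0.63) and with the deletion mixture (0.61), and of the deletion diet with its mixture (0.46) were 0.07 without array 4, 0.15 without array 4, 0.32 without array 9 and 0.09 without array 3. With separate Cladosporium arrays for each side of a pair, the 6 correlations were -0.48 to -0.14, against -0.29 to 0 in the simulated data.

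The deletion diet against the wild-type diet isolated the loss of LaeA in a pure Aspergillus food. Fcc00137, the cyclopropane fatty acyl phospholipid synthase-like gene, was higher on the deletion diet by log2 0.87 (SE 0.20), 0.69 to 0.99 with each array left out, and by 0.26 in the separate-channel fit. Uncharacterised fly-like Fcc01311 (LD46156p) was higher by 1.13 (SE 0.32) and Fcc02589 (GA19574) by 0.80 (SE 0.27), and Fcc06058 (CG14377) stood at -1.19 (SE 0.38). The separate-channel fit gave 0.80 for Fcc01311, 0.72 for Fcc02589 and -0.40 for Fcc06058. Isopenicillin N synthase, Fcc00057 and Fcc01821, was at 11.89 ± 0.71 and 8.70 ± 0.79 log2 on the deletion diet (SD, n = 4), against 11.87 ± 1.55 and 8.73 ± 1.52 on the wild-type diet.

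No group was called by camera here. The closest were digestive and lysosomal proteases, higher on the deletion diet in 17 of 20 (median 0.25, adjusted p = 0.0715, adjusted p = 0.521 with an estimated correlation), with a serine proteinase (Fcc04942) at 1.13 (SE 0.81). Lipid metabolism genes were higher in 13 of 16 (adjusted p = 0.0779), with lipase H (Fcc03348) at 1.58 (SE 0.80) and a fatty acid binding protein (Fcc00212) at 0.49 (SE 0.22). Ribosomal proteins were lower in 26 of 36 (median -0.09, adjusted p = 0.0715). Muscle genes were lower in 5 of 7 (median -0.16), nervous system genes were split 4 to 4 (median 0.05), egg proteins were higher in 2 of 3, and probes of the fungal or bacterial group were lower in 9 of 13 (median -0.13, adjusted p = 0.274). Without array 3 camera called 3 groups. By limma, 0 genes were called (smallest adjusted p = 1), 49 had an unadjusted p under 0.05, 45 higher and 4 lower, and the separate-channel fit called 0. The count of 49 ran from 22 to 150 with each array left out.

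Between the mixtures the same loss of LaeA was compared with Cladosporium present. Niemann-Pick C2-like Fcc05876, a sterol-binding lysosomal protein, was lower on the deletion mixture at log2 -1.75 (SE 0.61, 95% CI -3.17 to -0.33). Its level was 7.03 ± 1.14 log2 on the deletion mixture and 8.27 ± 0.85 on the wild-type mixture (SD, n = 4), and the difference ran from -2.24 to -1.20 with each array left out. The deletion mixture pools of arrays 4 and 10 stood at 6.28. Spodomicin, above background in none of the deletion mixture pools, stood at 6.11 to 6.22 there, so the size of this fold is uncertain. Fcc06001 (similar to CG3153) stood at -2.51 (SE 0.95), from -3.27 to -1.75 with each array left out and Fcc06058 at 1.02 (SE 0.38), 0.67 without array 10. In the separate-channel fit they stood at -1.24 (Fcc05876), -2.24 (Fcc06001) and 0.53 (Fcc06058). Over all settings they ran from -2.99 to -1.20 (Fcc05876), -3.37 to -1.39 (Fcc06001) and 0.37 to 1.37 (Fcc06058). Spodomicin (Fcc04856) was lower on the deletion mixture too, but was above background in none of its pools, and its value moved from -2.06 to -0.19 with the processing.

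Ribosomal proteins were higher on the deletion mixture in 31 of 36 (median 0.14, camera adjusted p = 1.54e-05, adjusted p = 0.539 with an estimated correlation), with S9 (Fcc06150) at 0.62 (SE 0.25). Esterases and other phase I enzymes were higher in 10 of 11 (median 0.25, camera adjusted p = 0.00439, adjusted p = 0.492 with an estimated correlation), with a flavin-containing monooxygenase (Fcc04244) at 0.53 (SE 0.23). Glutathione S-transferases were higher in 13 of 15 (median 0.14, camera adjusted p = 0.0161, adjusted p = 0.514 with an estimated correlation), with Fcc01480 at 0.50 (SE 0.28). Muscle genes were higher in 6 of 7 (median 0.15), nervous system genes in 7 of 8 (median 0.12), egg proteins in 3 of 3 (median 0.16) and probes of the fungal or bacterial group in 7 of 13 (median 0.10, adjusted p = 0.159). Without array 4, which carried both mixtures, the ribosomal group had adjusted p = 0.922, and the esterases (0.846) and glutathione S-transferases (0.448) turned in direction; without array 3 the last 2 had 0.115 and 0.0743. With a dye term for each slide the ribosomal, esterase and glutathione S-transferase groups had adjusted p = 4.33e-08, 0.0155 and 0.465, and on slide 1 alone 1.12e-06, 0.0877 and 0.819. Limma called 0 genes (smallest adjusted p = 0.999), 21 had an unadjusted p under 0.05, 7 higher and 14 lower, and the separate-channel fit called 0.

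Whether the effect of LaeA differed between pure and mixed food was tested as the difference of those 2 differences. It was positive for Niemann-Pick C2-like Fcc05876, at log2 3.44 (SE 0.86), 2.47 to 4.42 with each array left out, and negative for Fcc06058, at -2.21 (SE 0.54). The separate-channel fit gave 1.72 for Fcc05876 and -0.93 for Fcc06058. Ribosomal proteins were lower in 33 of 36 (median -0.23, camera adjusted p = 1.78e-06, adjusted p = 0.587 with an estimated correlation). Glutathione S-transferases were lower in 14 of 15 (median -0.14, camera adjusted p = 0.0468, adjusted p = 0.587 with an estimated correlation). Without array 4 the ribosomal group had adjusted p = 0.381 and the glutathione S-transferases turned in direction (0.682), the latter call also ending without array 1, 2, 3 or 7, from 0.0511. Given a dye term for each slide the 2 groups had adjusted p = 3.93e-12 and 0.185, and on slide 1 alone 2.33e-08 and 0.606. The limma fit called 0 genes (smallest adjusted p = 1), 57 had an unadjusted p under 0.05, 43 higher and 14 lower, and the separate-channel fit called 0.

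The wild-type mixture against the wild-type diet asked what Cladosporium in the food does beside wild-type Aspergillus. Niemann-Pick C2-like Fcc05876 was higher on the mixture by log2 2.17 (SE 0.61, 95% CI 0.75 to 3.59), 1.63 without array 5 and 3.15 without array 8, though the array carrying both diets gave 0.24. Fcc06001 was higher by 2.98 (SE 0.95), 2.22 without array 5 and 4.50 without array 8, and 0.03 on the array carrying both diets. Fcc06058 stood at -1.25 (SE 0.38), -0.73 without array 8, and Fcc04434, similar to an unnamed fish protein, at -1.85 (SE 0.51). The separate-channel fit gave 0.91 for Fcc05876, 1.30 for Fcc06001, -0.95 for Fcc06058 and -1.90 for Fcc04434.

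Probes of the β-lactam biosynthesis group, which holds the β-lactamase-like Fcc01834 too, were lower on the mixture in 6 of 7 (median -0.44, camera adjusted p = 0.00154, adjusted p = 0.386 with an estimated correlation), with Fcc00057 at -0.93 (SE 0.45), Fcc01821 at -0.77 (SE 0.40) and Fcc00170 at -1.33 (SE 0.68). Ribosomal proteins were lower in 35 of 36 (median -0.12, camera adjusted p = 6.94e-06, adjusted p = 0.651 with an estimated correlation). ABC transporters were lower in 6 of 7 (median -0.09, camera adjusted p = 0.0203, adjusted p = 0.321 with an estimated correlation), among them an MRP-type exporter (Fcc00181) at -0.40 (SE 0.23). Probes of the fungal or bacterial group were lower in 11 of 13 (median -0.16, camera adjusted p = 0.0293, adjusted p = 0.321 with an estimated correlation), with an Aspergillus-like hypothetical protein (Fcc00343) at -0.59 (SE 0.65). Muscle genes were lower in 6 of 7 (median -0.19), nervous system genes were split 4 to 4 (median 0.00) and 1 of 3 egg protein probes was higher. The ribosomal call was lost without array 4 (adjusted p = 0.292), the β-lactam call without array 1, 4 or 5 (0.0781 to 0.112), the ABC transporter call without array 1, 4, 5 or 9 (0.101 to 0.146), and the fungal or bacterial call without array 1, 4, 5, 7, 8 or 9 (0.0529 to 0.227). Under a dye term for each slide the β-lactam, ribosomal, ABC transporter and fungal or bacterial groups had adjusted p = 0.02, 1.65e-08, 0.202 and 0.0865, and on slide 1 alone 0.0897, 0.0118, 0.207 and 0.0731. In this comparison limma called 0 genes (smallest adjusted p = 1), 34 had an unadjusted p under 0.05, 22 higher and 12 lower, and the separate-channel fit called 0.

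Against the midpoint of its component diets on the log2 scale, the wild-type mixture was higher for Fcc06001 by log2 2.75 (SE 0.82), for Fcc05876 by 1.63 (SE 0.52) and for alpha-tectorin-like Fcc05235 by 1.72 (SE 0.59). Effects that add in log2 would give this midpoint only with equal shares of the fungi eaten, and the labels give no shares. Without array 5 Fcc06001 stood at 1.60 and Fcc05876 at 0.82, and the separate-channel fit gave 1.67, 0.81 and 0.83 for the 3 genes. Glutathione S-transferases lay below the midpoint in 11 of 15 (median -0.16, camera adjusted p = 0.028, adjusted p = 0.81 with an estimated correlation). Muscle genes lay below it in 6 of 7 (median -0.32, camera adjusted p = 0.0187, adjusted p = 0.81 with an estimated correlation). Without array 4 both groups turned in direction (adjusted p = 0.992), and both calls ended without array 10 (from 0.188 for muscle and 0.249 for glutathione S-transferases). With a dye term for each slide they had adjusted p = 0.0336 for glutathione S-transferases and 0.0286 for muscle, and on slide 1 alone 0.984 for both. By limma, 0 genes were called (smallest adjusted p = 1), 33 had an unadjusted p under 0.05, 19 higher and 14 lower, and the separate-channel fit called 0.

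The deletion mixture against the deletion diet asked what Cladosporium does beside the deletion strain. Fcc04350 (similar to CG7076) stood at log2 -4.99 (SE 1.31), -6.29 to -4.36 with each array left out and -1.85 in the separate-channel fit. The antimicrobial peptide Alo2 (Fcc05968) was lower, at -0.94 (SE 0.29, 95% CI -1.62 to -0.26), and so was lectin 2a (Fcc02832), a sugar-binding protein, at -1.20 (SE 0.42), though at -0.06 on the array carrying both diets and -1.86 without array 3. Fcc00137 stood at -0.61 (SE 0.20), but at -0.10 in the separate-channel fit, where Alo2 stood at -0.59 and lectin 2a at -0.63. Over all settings lectin 2a ran from -2.19 to -0.36. Innate immunity genes were lower in 3 of 5 (median -0.22, camera adjusted p = 0.0168, adjusted p = 0.461 with an estimated correlation). Ribosomal proteins were higher in 27 of 36 (median 0.09, camera adjusted p = 0.0168, adjusted p = 0.993 with an estimated correlation). The immunity call was lost without array 2, 3, 4, 9 or 10 (adjusted p 0.0868 to 0.329) and the ribosomal call without array 3, 4, 6 or 9 (0.233 to 0.812). Given a dye term for each slide the immunity and ribosomal groups had adjusted p = 0.151 and 6.04e-09, and on slide 1 alone 0.248 and 5.94e-09. Limma called 0 genes (smallest adjusted p = 1), 43 had an unadjusted p under 0.05, 4 higher and 39 lower, and the separate-channel fit called 0.

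Against the midpoint of its components, the deletion mixture was lower for Alo2 (Fcc05968), at log2 -0.87 (SE 0.25), and for the chaperone Hsp40 (Fcc00785), at -0.39 (SE 0.15). It was higher for ATP synthase subunit 6 (Fcc00661) by 0.56 (SE 0.22) and enoyl-CoA hydratase 1 (Fcc01668) by 0.37 (SE 0.13). Hsp40 stood at -0.24 without array 10 and ATP synthase subunit 6 at 0.88 without array 3, and the separate-channel fit gave -0.47 for Alo2, -0.27 for Hsp40, 0.53 for ATP synthase subunit 6 and 0.36 for enoyl-CoA hydratase 1. Innate immunity genes lay below the midpoint in 4 of 5 (median -0.25, camera adjusted p = 0.00571, adjusted p = 0.328 with an estimated correlation). Adjusted over the list alone, 1 of these 5 genes passed, Alo2 (adjusted p = 0.0498), against 0 over all genes. Ribosomal proteins lay above it in 31 of 36 (median 0.11, camera adjusted p = 5.82e-05, adjusted p = 0.883 with an estimated correlation). The immunity call was lost without array 3, 4 or 10 (adjusted p 0.064 to 0.448) and the ribosomal call without array 3, 4 or 5 (0.181 to 0.415). Under a dye term for each slide the 2 groups had adjusted p = 0.623 and 7.7e-09, and on slide 1 alone 0.808 and 2.36e-10. The limma fit called 0 genes (smallest adjusted p = 1), 28 had an unadjusted p under 0.05, 6 higher and 22 lower, and the separate-channel fit called 0.

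Across all 5 diets together, the described genes with the smallest p were Fcc06270 (moderated F = 7.9), Fcc00137 (F = 6.96), Fcc04350 (F = 5.84), Fcc04434 (F = 4.62) and Niemann-Pick C2-like Fcc05876 (F = 4.32). The level of Fcc06270 was 9.82 ± 0.34 log2 (SD, n = 4) on Cladosporium, 9.19 ± 0.65 on the wild-type diet, 9.52 ± 0.47 on the deletion diet, 9.55 ± 0.39 on the wild-type mixture and 9.59 ± 0.41 on the deletion mixture. In this comparison limma called 0 genes for any diet difference (smallest adjusted p = 1), 21 had an unadjusted p under 0.05, and the separate-channel fit called 0.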

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

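The tests of spot noise, a slide effect, reversed dye labels, fungal RNA in the gut, reassigned diet labels and shared pool variation were chosen after the result was seen; the probe sequence test was chosen before. In each diet the 4 pools were searched for a pool far from the others, for 35 genes: those named by the rule and the probes similar to isopenicillin N synthase or the penicillin tripeptide synthetase. It was found in 11 of 175 groups, where chance alone gives about 1 in 20, or 8.8.

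The wild-type pool on array 1 stood apart for 4 probes: 14.18 log2 for isopenicillin N synthase Fcc00057 (others 10.91 to 11.28), 11 for isopenicillin N synthase Fcc01821 (7.8 to 8.24), 14.95 for Fcc00086, similar to a nematode protein (11.16 to 11.35), and 11.54 for the DC2-like Fcc04101 (11.17 to 11.22). Deletion diet pools stood apart at 6.61 for Fcc00255 (others 9.7 to 10.13) and at 5.97 for the penicillin tripeptide synthetase Fcc00590 (6.19 to 6.24). Over all diets Fcc00590 ran from 5.92 to 6.58, near the level at which spodomicin was not above background, so its gap means little. Cladosporium pools did so at 7.57 for Fcc00758 (8.14 to 8.2) and at 10.93 for Fcc04617 (8.77 to 8.92). Wild-type mixture pools did so at 11.48 for Fcc01311 (10.55 to 10.6) and at 6.44 for Fcc02341 (8.22 to 8.51), and a deletion mixture pool at 9.86 for Fcc06001 (6.64 to 6.7).

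The isopenicillin N synthase probes Fcc00057 and Fcc01821 were higher on the Aspergillus-containing diet on each of the 4 arrays that carried Cladosporium (by 2.27, 0.81, 0.31 and 1.44 for Fcc00057), and the model put them 0.60 (SE 0.45) and 0.56 (SE 0.40) higher on the wild-type mixture, where the mean levels over pools had the opposite direction (10.66 against 11.10 for Fcc00057), while another such probe, Fcc05602, was lower on 1 of the 4 arrays (-0.3). Fcc00057 and Fcc01821 were named by their p in a fit that held these arrays, so the shared direction is no separate support. The sequences of the 2 probes share a run of at most 5 bases of 60, which argues against 1 stretch of sequence binding both. Transcripts were not compared with the probes, so transcripts of similar genes binding both probes at different sites cannot be excluded. The ratios of the 2 probes correlated at 0.97 over arrays. Whether the 2 probes lie on 1 transcript was not tested, and the shared run cannot tell. Penicillin gene RNA of Aspergillus in the gut contents should be lower on the deletion strain, since LaeA is needed for its expression, but the deletion minus wild-type difference of -0.11 (SE 0.48, 95% CI -1.34 to 1.13) has an interval too wide to decide. Of 11 probes with an Aspergillus hit, 9 were higher and 2 lower on the wild-type than on the Cladosporium diet, by a median of 0.09 and at most 1.04. Fcc00057 also stood at 9.955 to 11.902 log2 in the Cladosporium pools, which ate no Aspergillus. Aspergillus RNA was thus not needed for a signal, though it may add to it. The wild-type pools other than that on array 1 lay at 10.91 to 11.28, within this range. An induction of the animals' own β-lactam genes by Aspergillus stays open beside fungal RNA and chance (limma adjusted p = 0.987 for both probes on the wild-type diet). The induction is an untested hypothesis, and a single pool carries much of the difference.

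Arrays 4 and 10 had the widest log2 ratios and left the largest residuals, 1.74 times those of the others. Spot noise is argued against, since the SD between replicate spots of these arrays was 0.83 times that of the others. A slide effect of 1 direction on both is argued against by the correlation of their ratios across genes, -0.63, although the deletion mixture was the Cy5 sample on both. Reversed dye labels on 1 of them cannot be told apart from other causes: array 4 correlated at -0.26 with the ratios predicted from slide 1 and array 10 at -0.01, but 8 of 10 arrays correlated below 0 with the prediction from the other 9. Turning the sign of array 4 or of array 10 lowered the residual mean square from 0.376 to 0.253 or 0.262, and a real difference between the deletion mixture pools of the 2 arrays stays open too.

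In the unweighted fit of spot means on all arrays, fewer genes than 5% had an unadjusted p under 0.05 in every comparison, but array weights gave more than 5% in 4 comparisons (254 to 469 genes), as did leaving out array 4 or 10 in some. Differences between pools shared by many genes may account for it, but were not shown. The first component of the residuals held 55.8% of their variation against 22.7% in simulated independent errors. The simulated errors had the same size on all arrays, while residuals of arrays 4 and 10 were 1.74 times those of the others. Larger errors on these arrays alone could also raise the share, so it cannot decide. The leading described genes of this component included a pancreatic lipase-related protein (Fcc02519) and a cellulase (Fcc05266) in 1 direction. The uncharacterised Fcc03882 and Fcc05079 went in the other. Of 100 random reassignments of the diet pairs to the arrays, 91 left a residual mean square as small as the real 0.376 (range 0.201 to 0.429). The diet labels may thus carry less signal than the differences between pools, or some array labels may be wrong. Arrays 4 and 10 may also dominate the result, since turning the sign of either alone gave 0.253 or 0.262. The reassignments were not run without these arrays, so they cannot tell these readings apart. These readings are not exclusive, and what made the pools differ was not measured.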

How the results depend on the processing

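The settings with spots as separate observations, the unconverged array weights, slide 1 alone, the dye term per slide for gene groups, and each left-out array for the correlations were chosen after seeing the data. Gene counts of 0 stayed 0 in 275 of 275 planned values over 23 settings, and 24 of 48 added values were 0. The 55 values of named genes were chosen by their p in the same data, with some genes repeated, so a kept direction is no separate support. They kept their direction in every setting that kept the probe (41 remained with signal over background in all 20 channels). Their size was less stable: 17 of the 55 moved by over 1.5 times when 1 array was left out, 40 in the separate-channel fit, all 40 toward 0, and 48 in at least 1 setting. The highest-signal probe and each probe by itself were not run, since each probe was treated as 1 gene. Where 1 array is left out, pools left alone in a dye are assumed to vary like the others. Median centring moved the largest median of all genes to 0.138 log2. Dim probes limit what can be seen: 693 probes had no signal over background in any channel.

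With the 3 spots as separate observations, genes called were 431 (wild-type against Cladosporium), 191 (deletion), 188 (wild-type mixture), 404 (deletion mixture), 237 (deletion against wild type), 100 (between mixtures), 102 (wild-type mixture against wild type), 144 (deletion mixture against deletion), 219 (interaction), 107 and 243 (wild-type and deletion mixture against their midpoints) and 718 (any diet), because copies of a spot count as replicates. With their correlation of 0.911 modelled, limma called 10, 28, 6, 0, 19, 7, 7, 30, 38, 6, 0 and 49 in that order. Unconverged array weights gave 42 for the deletion diet against Cladosporium, where the default weights gave 0, and slide 1 alone gave 1; the cause was not tested.

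Gene groups called by camera numbered 3, 1, 3, 2, 0, 3, 4, 2, 2, 2 and 2 in the order of the first 11 comparisons above. They fell to 0 in all 10 with calls by fry and by camera with the estimated correlation, which allows for genes of a group varying together. On ranks the count was 1 (wild type against Cladosporium), 1 (deletion mixture against Cladosporium), 2 (deletion against wild type), 4 and 1 (midpoints). Without a dye intercept it was 1 for the deletion mixture against Cladosporium and against the deletion diet and 1 for the interaction. With no filter it was 1 (wild type), 0 (deletion) and 0 (wild-type mixture) against Cladosporium, 1 (interaction) and 0 (wild-type midpoint). Median centring gave 0 (deletion) and 1 (deletion mixture) against Cladosporium, 5 (between mixtures), 1 (deletion mixture against deletion) and 6 (wild-type midpoint). Slide 1 alone gave 1 (wild-type mixture against Cladosporium), 1 (deletion against wild type), 1 (wild-type mixture against wild type), 1 (interaction) and 0 (wild-type midpoint). A dye term per slide gave 1, 2 and 1 (wild type, deletion and deletion mixture against Cladosporium), 6 (between mixtures), 2 (wild-type mixture against wild type), 4 and 1 (midpoints). With each array left out the counts ran from 1 to 5, 1 to 3, 0 to 4, 1 to 4, 0 to 3, 0 to 5, 0 to 6, 0 to 5, 0 to 5, 0 to 5 and 0 to 3 in the same order; the cause was not tested.

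Without array 4, 4 of the 24 group calls were kept, and 5 turned in direction: between the mixtures the esterases (adjusted p from 0.00115 to 0.846 over the left-out arrays) and glutathione S-transferases (0.0148 without array 10, 0.448 without array 4), in the interaction glutathione S-transferases (0.00512 to 0.682), and against the wild-type midpoint glutathione S-transferases (0.00776 to 0.992) and muscle (0.00349 to 0.992). Each higher value is that without array 4, and the cause was not tested. Correlations of fold changes reversed when the Cladosporium arrays were split between the sides of a pair: -0.14 (wild type and deletion), -0.32 (wild type and its mixture), -0.20 (wild type and deletion mixture), -0.48 (deletion and wild-type mixture), -0.46 (deletion and its mixture) and -0.18 (mixtures). Simulated data without diet differences gave 0, -0.14, 0, -0.29, -0.14 and 0 in that order, so some of the split values still shared errors. With each array left out they ran from 0.19 to 0.76, 0.15 to 0.80, 0.32 to 0.78, 0.50 to 0.82, 0.09 to 0.64 and 0.07 to 0.79.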

Other observations

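The test of digestive and detoxification genes varying together was chosen after the result was seen, while the test of Cladosporium against the other diets and the splits of the samples were chosen before. Of the groups not yet described for the wild-type against the Cladosporium diet, lipid metabolism genes were lower in 11 of 16 (median log2 -0.18, camera adjusted p = 0.149), proteases in 13 of 20 (-0.07, 0.149), chitin and cuticle genes in 5 of 6 (-0.25, 0.149), esterases and other phase I enzymes in 8 of 11 (-0.17, 0.149), glutathione S-transferases in 12 of 15 (-0.08, 0.229), heat shock proteins in 7 of 9 (-0.04, 0.162) and innate immunity genes in 4 of 5 (-0.22, 0.251). Proteasome and ubiquitin genes were higher in 12 of 17 (median 0.08, adjusted p = 0.149), oxidative phosphorylation genes in 9 of 15 (0.06, 0.621) and ABC transporters in 6 of 7 (0.11, 0.343). Antioxidant defence genes were higher in 4 of 11 (-0.02, 0.98) and translation factors in 3 of 8 (-0.05, 0.98). Too small to test were cell cycle genes (3 of 3 higher, median 0.28), a juvenile hormone esterase (Fcc02166, -0.33, SE 0.18), a secreted ferritin for metal binding (Fcc04961, 0.00, SE 0.14) and the UDP-glycosyltransferases and sulfotransferases, of which 0 probes were measured.

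Many gene groups varied together from array to array, digestive genes among them. Over the 10 arrays the mean log2 ratio of the carbohydrate hydrolases was correlated with that of the other 18 groups tested. It followed lipid metabolism genes (r = 0.95, permutation p = 7e-05, adjusted 0.00063; rho = 0.94, permutation p = 0.00016, adjusted 0.0014), heat shock proteins (r = 0.93, permutation p = 4e-05, adjusted 0.00063; rho = 0.95, permutation p = 0.00016, adjusted 0.0014) and cytochrome P450 genes (r = 0.89, permutation p = 0.00078, adjusted 0.0036; rho = 0.82, permutation p = 0.0057, adjusted 0.032). Esterases and other phase I enzymes (r = 0.86, permutation p = 8e-04, adjusted 0.0036; rho = 0.78, permutation p = 0.011, adjusted 0.04) and glutathione S-transferases (r = 0.81, permutation p = 0.0033, adjusted 0.012; rho = 0.81, permutation p = 0.007, adjusted 0.032) followed it too. For proteases (r = 0.75, permutation p = 0.013, adjusted 0.036; rho = 0.70, permutation p = 0.032, adjusted 0.082) and muscle (r = 0.74, permutation p = 0.014, adjusted 0.036; rho = 0.72, permutation p = 0.024, adjusted 0.072) only r passed the adjustment, and for the other 11 groups neither did. Without arrays 2 and 10, the farthest from the median, r was 0.90, 0.86, 0.82, 0.75, 0.70, 0.69 and 0.51 in the order given, and on the 8 arrays of slide 1 it was 0.91, 0.89, 0.84, 0.76, 0.65, 0.65 and 0.38, while slide 2 held too few arrays. The r of 0.81 between carbohydrate hydrolases and glutathione S-transferases restates the pattern that prompted it, and array ratios carry diet and array differences beside those between pools, so whether digestive and detoxification genes vary together between pools stays open. Heat shock proteins followed the hydrolases as closely, so the relation is not particular to these groups. A difference between pools in feeding or moulting state is a candidate explanation that was not tested.

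A common shift of genes by Aspergillus in the food was tested as the mean of the other 4 diets against Cladosporium. Limma called 0 genes (smallest adjusted p = 0.98), and 47 had an unadjusted p under 0.05. The named genes with the smallest p were Fcc06270 at log2 -0.76 (SE 0.15, lower on 4 of 4 arrays), Fcc00086 at 1.24 (SE 0.35, higher on 4 of 4) and isopenicillin N synthase Fcc00057 at 1.21 (SE 0.35, higher on 4 of 4). Genes picked for a small p in this fit tend to lie on 1 side on these arrays, so the shared directions are no separate support. In a fit of 2 groups 120 genes had an unadjusted p under 0.05, and 37 of 100 splits of the samples gave as many (median 88, range 5 to 1824), so a common shift was neither shown nor excluded.

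Since the real count of called genes was 0 in each comparison, every other split of the samples had to give as many, and these splits cannot test the grouping. The number of genes at an unadjusted p under 0.05 can: 17 to 34 of the 35 splits gave as many as the real one in the comparisons between 2 diets, 71 of 94 for the interaction, 91 of 100 and 79 of 99 for the midpoints and 95 of 97 for any diet, so a chance arrangement of the pools is not excluded. By called genes, for the 8 comparisons between 2 diets it was 35 of 35 splits, and the highest other count was 1 (wild type against Cladosporium), 654 (deletion against Cladosporium), 1 (wild-type mixture against Cladosporium), 1246 (deletion mixture against Cladosporium), 3 (deletion against wild type), 1067 (between mixtures), 2 (wild-type mixture against wild type) and 4 (deletion mixture against deletion). It was 94 of 94 splits for the interaction (highest 956), 100 of 100 for the wild-type mixture against its midpoint (150), 99 of 99 for the deletion mixture against its midpoint (805) and 97 of 97 for any diet (955). In the comparisons with 654, 1246 and 1067, only 1 other split called over 100 genes. The splits with 1246 and 1067 put the deletion mixture pools of arrays 4 and 10 in different groups. That with 1246 also swapped the diets of array 10, and that with 654 moved the Cladosporium pool of array 10. Many of the 35 splits that did not call over 100 genes separate the same pools, so no structure of the samples follows from this. On slide 1 alone limma called 1 gene for the deletion diet against Cladosporium and 0 in the other comparisons.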
